A study of Brassica rapa subsp. chinensis with 5 samples.

How the data were processed

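Small RNA was sequenced from 4 Chinese cabbage libraries (Brassica rapa ssp. chinensis) and 1 Arabidopsis thaliana library (ecotype Landsberg erecta, Ler) on an Illumina GAII instrument, per the labels. The labels of the Ler sample conflict: its source says Arabidopsis thaliana and its organism field Brassica rapa, and it was treated as Arabidopsis. The deposited values are raw read counts: each of the 5 lists gives distinct sequences assigned to the chloroplast with the number of reads of each, per the readme deposited with them. The adapter trimming, the mapping tool, the number of mismatches allowed and the chloroplast genome used by the authors are not given in the sources used here. The lists hold the chloroplast part of each library, so their totals are not the depth of the libraries, and a change in chloroplast RNA as a whole cannot be measured. The Chinese cabbage libraries held 1523164 and 1278752 counts (heat replicates 1 and 2) and 2162001 and 1523433 counts (control replicates 1 and 2). The Ler library held 787272 counts.

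Chinese cabbage and Arabidopsis RNA were sequenced at different centres, per the labels. The labels give each Chinese cabbage library its own line number (Wu-11 to Wu-14), so a difference between lines, if the numbers mark lines, is not separable from the treatment. No label says that the replicates are separate plants or pools, and p-values then measure only the spread between these libraries. The chi-square statistic per degree of freedom between replicates was 6.19 in heat and 7.52 in control over the sequences, so neither pair was a library deposited again.

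Changes per sequence were tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F-test, TMM scaling and filterByExpr at a minimum count of 10, over the 4 Chinese cabbage libraries with group as the only term. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM of the list total, scaled by TMM, and refer to the chloroplast lists only.

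The planned test per gene needed an annotated chloroplast genome. None was used here, so the planned fallback was applied: sequences that share 16 bases with universal chloroplast primers, in either orientation, were summed for 6 genes. The scaling factors of the fit across sequences were used for them, since 6 sums give no scaling of their own. These families held 0.104% to 0.158% of the counts.

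A wider placement was added after the data were seen, in place of a gene test limited to the primer families. The reads of the 4 Chinese cabbage libraries were joined into contigs through shared runs of 15 bases, which gave 992 contigs of at least 40 nt with 80065 bases in all. Ribosomal RNAs, 30 transfer RNA genes and 76 proteins were then searched in the reads and contigs with gene and protein sequences written from textbook knowledge of plant chloroplasts. The RNA sequences were corrected by a vote of the reads, and a part was kept when reads covered at least 80% of it, which held for 39 of 40 parts. In Ler these 39 parts were corrected by the Ler reads and used whatever their coverage, 63.9% at the lowest. Protein matches started from 8 identical residues: 74 proteins gave 503 matches, while the same proteins with shuffled residues gave 1. Matches covered from 11.0% of a protein (rpoB) to 100.0%, with 42.4% for rpoA and 34.9% for rps3. A gene sum may thus cover part of a gene, and unmatched coding parts can count as outside genes. Gene names in the text rest on this search and not on a genome, and no chromosome position is given. The ycf2 protein was added to the search after a look at the gene results, which were computed without it as well. Reads of at least 15 nt were placed without a mismatch, on the sense strand, in the gene that held their midpoint. Of the counts in reads of that length, 88.5% to 93.1% were placed in genes in this way, and 98.0% to 98.2% with antisense reads and contig stretches outside genes included. The contigs were built from these same reads, so a high placed share is no check on them. Sequences found in several genes were left out of the gene sums and held at most 0.084% of the counts. Genes that overlap or lie end to end, such as atpB and atpE, can trade reads at their borders. In a test on 1855 simulated fragments, 99.7% returned to their gene or to a sequence shared with it, and 0 of 7655 shuffled reads were placed. The fragments were cut without errors from the same gene sequences and contigs on which they were then placed. The test thus checks the placing step only and cannot show that a gene name, contig or border is right.

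Both fits were tested on simulated data drawn from the real means and spread. For the sequence comparison, with 7980 sequences, 22% of 100 changed by 2-fold and 82% of 100 changed by 4-fold were recovered, and 5.5% of the calls were false (6 calls). For the gene comparison, with 106 genes, 50% of 10 changed by 1.5-fold and 100% of 10 changed by 2-fold were recovered, and 6.2% of the calls were false (1 call). The data gave 50 calls among the genes, so this simulation does not show how the scaling behaves with that many changes.

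The tests, the gene lists, the rule for named genes and most of the other settings named below were fixed before the data were examined. The lists were tested with fry and camera (limma 3.58.1), camera with a preset correlation of 0.01 and with an estimated one, for lists with at least 3 measured genes. Calls from fry are those of its directional test, and its mixed test was added to the text after the data were seen. Shares of counts were compared with an exact permutation test. With 2 libraries against 2 its smallest two-sided p is 0.33, so it cannot pass 0.05 and no call is made from it. Shares in the Ler library carry exact 95% binomial intervals, which cover counting error only because reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 counts.

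The rule for named genes took the 4 ribosomal RNAs, the 5 transfer RNA and 5 protein-coding genes with the highest control CPM, and the 10 highest and 10 lowest log2 fold changes among genes past the threshold whose heat libraries lay on the same side of both controls. For sequences it took the 5 most abundant in control and the 6 highest and 6 lowest log2 fold changes after keeping the most abundant of sequences that share 16 bases. For Ler it took the 5 most abundant genes and collapsed sequences. The alternatives were RLE scaling, totals without TMM, no filter, a minimum count of 50, DESeq2 1.42.0, the replicate number as a block, each library left out, shares of distinct sequences, shares without the 10 most abundant sequences, other windows for transfer RNA ends, and other minimum counts. Added later were TMM factors from protein-coding genes, the removal of reads of 36 nt, and all fits on contigs. Stretches of contigs outside the placed genes were summed per contig and strand and tested in the same way. They were scaled by TMM factors of their own at the start, and the factors of the fit across sequences were adopted after those calls had been seen, which turned the balance of calls. Both are reported.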

Results

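Small RNA reads from chloroplasts were compared between Chinese cabbage seedlings held at 46 °C for 1 h and control seedlings held at 22 °C for 1 h, with 2 libraries per group. The RNA came from the above-ground parts of 3-week-old plants of a heat-sensitive inbred line. The labels number the line differently in each library (Wu-11 and Wu-12 in heat, Wu-13 and Wu-14 in control). A further library came from untreated whole seedlings of Arabidopsis thaliana, ecotype Landsberg erecta (Ler), per its source label, while its organism field names Brassica rapa. Total counts in the chloroplast lists ranged from 1278752 to 2162001 in Chinese cabbage, over 78299 to 116210 distinct sequences per library. In all, 27893 sequences occurred in each of the 4 Chinese cabbage libraries, and they held 93.6% to 94.9% of each library's counts. The Ler list held 787272 counts in 157750 distinct sequences. No mature sequence of 20 nuclear microRNAs occurred in any list, which allows a share of at most 0.000381% for each in the shallowest library.

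The comparison by RNA class asked which chloroplast transcripts the small RNAs came from and whether heat moved their balance. Fragments of ribosomal RNA made up 50.5% ± 4.40 of the control counts and 43.9% ± 4.67 of the heat counts (SD, n = 2 each). Fragments of transfer RNA made up 33.0% ± 4.07 in control and 38.7% ± 3.69 in heat. Reads in protein-coding genes held 2.73% ± 0.273 in control and 2.20% ± 0.0993 in heat. Contig stretches outside the placed genes held 5.02% ± 0.720 in control and 7.92% ± 0.792 in heat. The most abundant of these stretches held 42665 and 48571 counts in heat and 32175 and 31487 in control. Its most abundant sequence overlapped the matched part of ndhB by 10 of its 22 nt, so the class may hold reads of that gene. Reads antisense to a placed gene were few, at 0.217% ± 0.0093 in control and 0.509% ± 0.0127 in heat. Chance alone parts 2 libraries from 2 in 33.3% of measures. For each of these 5 classes both heat libraries lay on the same side of both controls, and the exact permutation p was 0.33, the smallest that 2 libraries against 2 can give. For ribosomal and transfer RNA the nearest heat and control libraries differed by less than the replicates did: 47.2% against 47.4% for ribosomal RNA and 36.1% against 35.9% for transfer RNA. The size of the differences depended on abundant sequences: over distinct sequences instead of counts, heat minus control was -0.861 points instead of -6.55 for ribosomal RNA, 1.69 instead of 5.68 for transfer RNA, -4.19 instead of -0.531 for protein-coding genes and 2.28 instead of 0.292 for antisense reads. For stretches outside the placed genes it was 1.99 points over distinct sequences instead of 2.90. Without the 10 most abundant sequences heat minus control was 9.82 for transfer RNA and -1.17 for protein-coding genes.

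**Figure D1:**
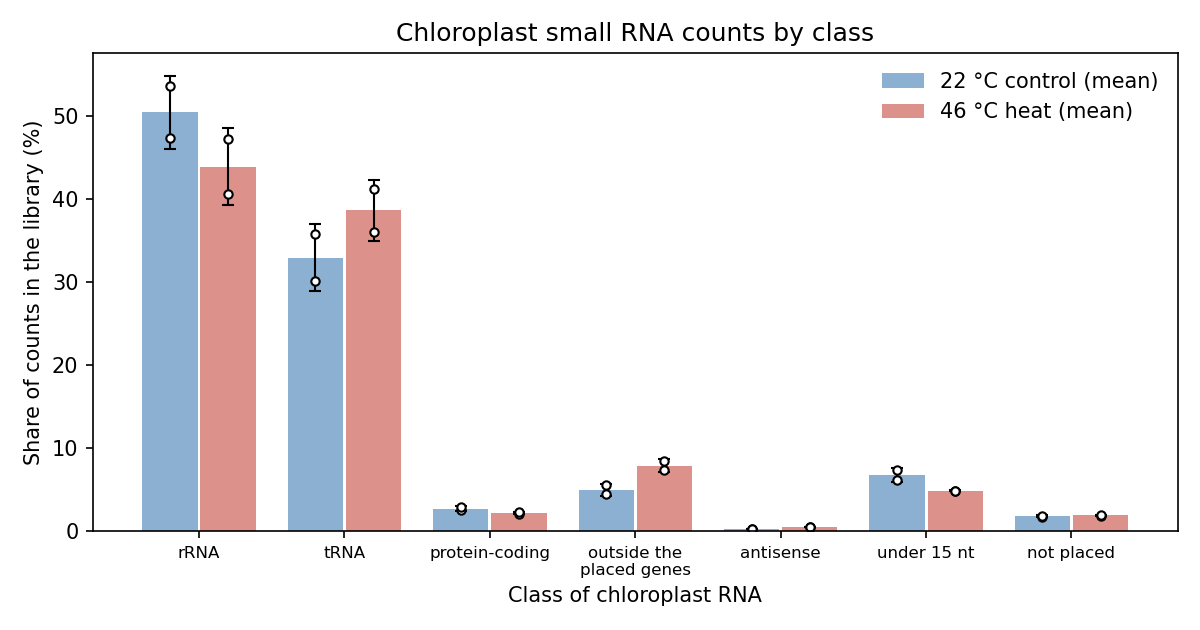
Share of counts in each library (%, vertical axis) by class of chloroplast RNA (horizontal axis). Bars are means of 2 libraries per group, error bars are SD and open points are the libraries; transfer RNA stood at 33.0% in control and 38.7% in heat, and stretches outside the placed genes at 5.02% and 7.92%.

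Reads were also compared gene by gene. In the planned comparison, sequences that share 16 bases with universal chloroplast primers stood for 6 genes, of which 5 had enough counts. The trnF-GAA and trnL-UAA families rose with heat, by 2.50 (SE 0.54, adjusted p = 0.00471 in edgeR) and 1.24 (SE 0.31, adjusted p = 0.00634) on the log2 scale, higher in both heat libraries than in both controls. They rested on few reads, 14, 16, 3 and 4 counts for trnF-GAA and 46, 40, 25 and 24 for trnL-UAA in heat replicates 1 and 2 and control replicates 1 and 2. The trnL-UAA family left out the gene's abundant 36-nt 5-prime sequence (27324 counts in control, 457 in heat). That sequence matches the primer over 16 bases only with 1 mismatch allowed. On contigs the whole gene held 82439 counts in control and 60946 in heat, so the family covers few of its reads. The families of rrn23, rbcL and rrn16 did not pass, with log2 changes of -0.53, -0.55 and -0.37, though rrn23 and rbcL did with a minimum count of 50 (adjusted p = 0.0439 for both) and on list totals (0.015 and 0.0271). Without either heat library neither family passed, and allowing 1 mismatch turned trnL-UAA to -0.89.

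With reads placed on contigs built from the reads themselves, a choice made after the data were seen, 106 genes could be tested. Their names rest on gene and protein sequences written from textbook knowledge and not on a genome of this plant. Transfer RNA genes led those that rose: 18 of 30 rose, 0 fell and 12 did not pass the test, and the count adjusted over the list alone was also 18. The trnN-GUU gene went from 2996 ± 716 CPM in control to 8693 ± 1391 CPM in heat (SD, n = 2 each), a log2 fold change of 1.54 (SE 0.19, adjusted p = 0.00115 in edgeR). The trnM-CAU gene rose by 1.06 (SE 0.10, adjusted p = 0.000562), trnC-GCA by 1.02 (SE 0.22), trnT-GGU by 1.00 (SE 0.10), trnW-CCA by 0.96 (SE 0.18) and trnF-GAA by 0.85 (SE 0.16). Among the most abundant transfer RNAs, trnA-UGC went from 20926 ± 871 to 37535 ± 2020 CPM (log2 0.84, SE 0.14) and trnP-UGG from 17685 ± 743 to 31943 ± 2035 CPM (log2 0.85, SE 0.14). Without the most abundant sequence of each gene these changes were 0.34 (adjusted p = 0.0284) and 0.41 (adjusted p = 0.00872). The most abundant of all, trnD-GUC, stood at 196667 ± 31234 CPM in control and 152668 ± 23356 in heat and did not pass (log2 -0.37, SE 0.20, adjusted p = 0.167). Neither trnL-UAA (log2 -0.22, adjusted p = 0.181) nor trnH-GUG (log2 0.08, adjusted p = 0.64) passed. Without reads of 36 nt trnL-UAA turned to 0.24, and with reads wholly inside the gene trnH-GUG passed at 0.84. The 6 intron-containing transfer RNAs had 2 that rose and 0 that fell, the same as adjusted over the list alone.

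Genes of the photosynthetic apparatus made up most of those that fell. The gene for the large subunit of Rubisco, rbcL, which fixes carbon dioxide, went from 8359.7 ± 179 CPM in control to 4375.8 ± 119 CPM in heat (log2 -0.93, SE 0.11, adjusted p = 0.00104). Of the 6 ATP synthase genes, which make ATP from the proton gradient, 4 fell and 0 rose: atpB by 1.32 (SE 0.10, adjusted p = 0.000296), atpE by 0.75 (SE 0.15), atpF by 0.74 (SE 0.11) and atpA by 0.64 (SE 0.11) on the log2 scale. Of 14 photosystem II genes measured, 7 fell and 0 rose, among them psbL by 1.03 (SE 0.17; 1.70 with reads wholly inside the gene), psbE by 0.75 (SE 0.11), psbC by 0.57 (SE 0.10) and psbA, which encodes the D1 protein of the reaction centre, by 0.50 (SE 0.11, adjusted p = 0.0076). Of 7 photosystem I genes with assembly factors, 4 fell and 0 rose, with psaC at -1.02 (SE 0.12) and psaB at -0.48 (SE 0.11). Among 5 cytochrome b6f genes, petD and petN fell and petG rose by 0.40. Of 11 NDH genes, which encode a complex of cyclic electron flow, ndhC fell by 0.50, 0 rose and 10 did not pass. On list totals without TMM 3 NDH genes rose and 0 fell, and 1 cytochrome b6f gene rose and 0 fell. Adjusted over the list alone, 4 ATP synthase and 5 photosystem I genes fell, 8 photosystem II genes fell and 1 rose, 3 cytochrome b6f genes fell and 1 rose, and 0 NDH genes passed. Without reads of 36 nt, whose share was lower in heat, 5 photosystem I, 8 photosystem II, 5 ATP synthase and 3 NDH genes fell, 3 cytochrome b6f genes fell and 0 rose, so that petG no longer passed, and 18 transfer RNA genes rose.

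**Figure D2:**
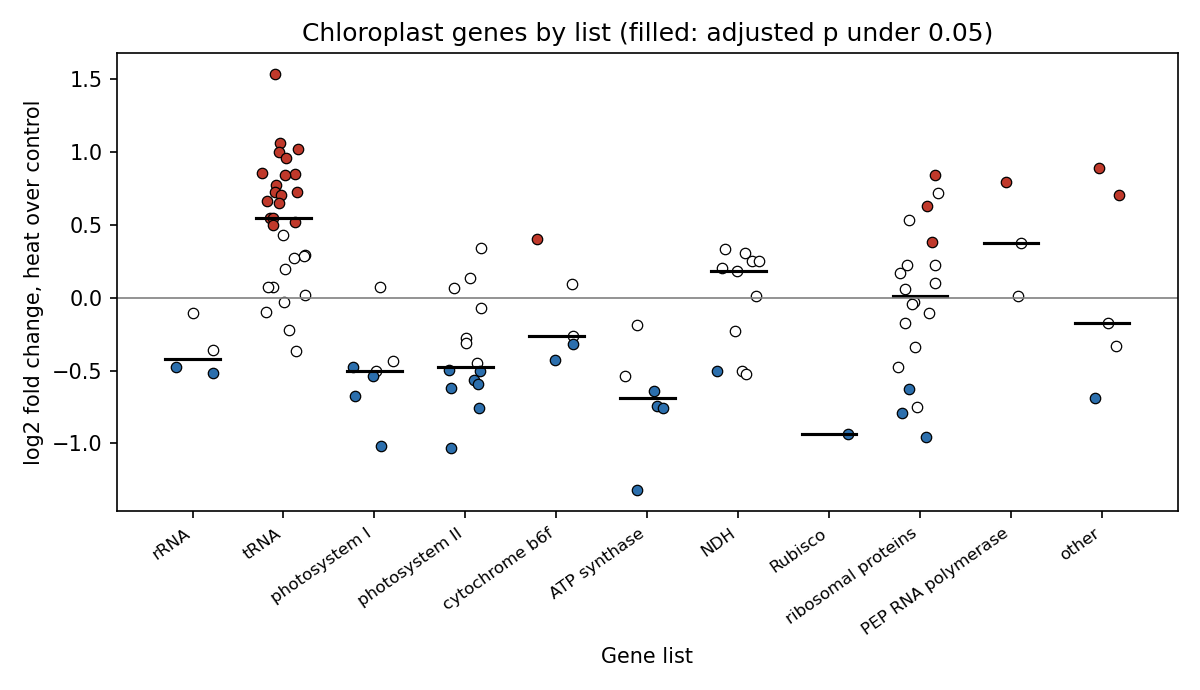
Log2 fold change of each gene, heat over control (vertical axis), for each gene list (horizontal axis). Each point is a gene from the fit over 2 heat and 2 control libraries, filled where the adjusted p was under 0.05 (red higher, blue lower in heat), and black lines are medians: 0.55 for transfer RNA and -0.69 for ATP synthase genes.

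Genes of the chloroplast's own gene expression went both ways. Of 4 ribosomal RNAs, rrn23 fell by 0.52 (SE 0.16, adjusted p = 0.0314) and rrn16 by 0.48 (SE 0.16, adjusted p = 0.0457). The rrn16 call was lost at about the same fold with RLE scaling (adjusted p = 0.0549), a minimum count of 50 (0.0617) and 1 mismatch allowed (0.0622), and both calls were lost without control replicate 1. The rrn4.5 gene, the largest source of reads with 363626 ± 60103 CPM in control and 283715 ± 48280 CPM in heat, did not pass (log2 -0.36, SE 0.22, adjusted p = 0.197), nor did rrn5 (log2 -0.10, SE 0.15). Of 20 ribosomal protein genes, 3 rose and 3 fell, against 6 and 3 on list totals and 2 and 5 without reads of 36 nt. Of the 20, rpl33 rose by 0.84 (SE 0.15) and rps18 by 0.63, and rpl14 fell by 0.96 (SE 0.29), rps3 by 0.79 (SE 0.17) and rps14 by 0.62. The rpl14 call was lost in DESeq2 (adjusted p = 0.0591) and without control replicate 2 (0.141). The most abundant of them, rpl23, did not pass (log2 0.23, adjusted p = 0.37), though it did on list totals (0.39, adjusted p = 0.0418) and without control replicate 2 (0.50, adjusted p = 0.000537). Of 3 measured genes of the plastid-encoded RNA polymerase, rpoA rose by 0.80 (SE 0.11, adjusted p = 0.00146). Among 5 other genes, ycf2, a large gene of the inverted repeat, rose by 0.89 (SE 0.10, adjusted p = 0.000985), ccsA rose by 0.70 and matK, an intron maturase, fell by 0.69 (SE 0.13, adjusted p = 0.00322). The matched part was 48.6% of the protein for ycf2, 23.6% for ccsA and 53.6% for matK. Among the 4 measured genes read by the nucleus-encoded RNA polymerase, ycf2 was the only one that passed. Adjusted over the list alone, 2 ribosomal RNAs fell, 2 ribosomal protein genes rose and 2 fell, 1 polymerase gene rose, 2 other genes rose and 1 fell, and 1 gene read by the nucleus-encoded polymerase rose.

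In total 25 genes rose and 25 fell in the edgeR quasi-likelihood fit. Its TMM factors centre the genes (median log2 change 0.01), so that balance cannot show or deny a shift common to all genes. The ycf2 protein was added to the search after a look at the genes, and without it 24 rose and 24 fell. Outside the rule for named genes, atpA, petD, petN, petG, ndhC, rps18, rps14, rpoA and ccsA were picked after their values were seen. These directions are relative to the scaling: on list totals without TMM the median log2 change of all genes was 0.19 instead of 0.01 and the split 38 to 18, with TMM factors from protein-coding genes it was 0.26 and the split 42 to 13, and rrn16 and rrn23 no longer passed under either. With the factors from protein-coding genes psbA (log2 -0.25), psbC (-0.32) and psaB (-0.23) did not pass either. With reads of 18 to 30 nt the split was 21 to 33, and without reads of 36 nt 23 to 33. The median stayed above 0 for transfer RNA and below 0 for ribosomal RNA, photosystem I, photosystem II and ATP synthase under each of these scalings. Without heat replicate 1 or without heat replicate 2, 0 of the 106 genes passed (39 and 42 at an unadjusted p under 0.05), while 0 of the 50 turned direction.

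As groups, the ATP synthase genes fell together (adjusted p = 0.011 in the directional fry test), and no other list passed in that test. In fry's mixed test, which ignores direction, 10 of 12 lists passed, all but ribosomal RNA (adjusted p = 0.115) and cytochrome b6f (0.0573). The camera test, which ranks a list against all other genes, placed transfer RNA higher (adjusted p = 4.69e-08) and ATP synthase (0.00864) and photosystem II (0.023) lower. With an estimated correlation the adjusted p was 0.507 for each of these 3 lists, and no list passed. For transfer RNA directional fry gave 0.0953 and for photosystem II 0.0805. The NDH median was 0.18 while its mean was -0.02, and fry and camera gave it opposite directions (adjusted p 0.974 and 0.993). The remaining lists did not pass in camera, with adjusted p from 0.0662 for photosystem I to 0.993 for ribosomal proteins. The fry call for ATP synthase was lost without control replicate 1 and without control replicate 2.

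Single sequences were tested next, since a small RNA study asks which fragments accumulate. Of 7980 sequences tested, 1346 rose and 568 fell with heat. Of 1590 tested fragments of transfer RNA, 813 rose and 80 fell, while of 4557 fragments of ribosomal RNA, 87 rose and 301 fell. Among 47 antisense sequences, 32 rose and 1 fell, and of 577 sequences outside the placed genes, 279 rose and 64 fell. Of 307 fragments of protein-coding genes, 31 rose and 15 fell, while most photosynthesis genes that passed as sums fell. The sequence and gene fits each used TMM factors of their own, so their directions are not on the same scale. In heat replicates 1 and 2 and control replicates 1 and 2 the factors were 0.987, 0.977, 1.04 and 0.997 over sequences. Over genes they were 1.04, 1.09, 0.900 and 0.985. Of 394 sequences under 15 nt, 24 rose and 71 fell, and of 508 not placed, 80 rose and 36 fell. Many of these are versions of the same fragment: calls with both heat libraries on the same side of both controls formed 298 groups of overlapping sequences among those that rose and 145 among those that fell. The most abundant sequence of the controls was the 5-prime 29 nt of trnD-GUC, GGGATTGTAGTTCAATTGGTCAGAGCACC, at 70913 ± 19601 CPM in control and 42029 ± 8258 CPM in heat (SD, n = 2 each), which did not pass (log2 -0.76, SE 0.29, adjusted p = 0.0579), though it did in DESeq2 (adjusted p = 0.0429), on list totals (0.0448) and with a minimum count of 50 (0.0152). Leaving out a control library moved it from -1.09 (adjusted p = 0.0211, without replicate 1) to -0.44 (0.476, without replicate 2). The other 4 of the top 5 were 3-prime ends of rrn4.5 that all stop at its last base, nucleotide 103. They were TAACAGACCGGTAGACTTGAAC (from nucleotide 82, log2 -0.29), AACAGACCGGTAGACTTGAAC (from 83, log2 -0.29), CAGACCGGTAGACTTGAAC (from 85, log2 -0.13) and AGACCGGTAGACTTGAAC (from 86, log2 -0.13), and none passed (adjusted p 0.477 to 0.792).

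The sequences with the highest and lowest fold changes were mostly rare, and most lay outside the placed genes. The 36-nt 5-prime sequence of trnL-UAA, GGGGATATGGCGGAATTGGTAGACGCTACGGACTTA, was abundant and in sense to its gene, with 15012 and 12312 counts in control and 222 and 235 in heat (log2 -5.46, SE 0.28, adjusted p = 2.49e-12), from nucleotide 1 to 36 of exon 1. Its 3-prime end is not known, since 36 nt is the longest read and the RNA may run on. CCTAAACCATAAGTCCTGGGG was at least 23.4-fold lower in heat with 58 and 38 counts in control and 0 in both heat libraries, against a floor of 3 counts over the group, so its rank among the lowest is not known. The others were TGTGACCAATTAACCAACCAACAAAACTAC (680 counts in control, 2 in heat), TTGCGTCGTTGTGCCTGGGCTGTGAGGGCT (366 and 1), ACTTTGTATCGCGCACATAACT (217 and 1) and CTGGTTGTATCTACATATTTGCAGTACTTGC (65 and 1), all on contigs with no placed gene. Among the highest, ACGATATACTGACTGAACTAT was at least 24.7-fold higher with 27 counts in each heat library and 0 in both controls, and its rank is not known either. GCGTAAGTCGTTAGAAGA, antisense to ndhD, had 200 counts in heat and 4 in control (log2 6.01, SE 0.45, adjusted p = 7.38e-10). The others were GGTAGACTCTAAAAAT (96 and 4 counts), CCGAACTGAACTAAGAGC antisense to trnW-CCA (26 and 1), ATGGGGTAGAGCCAAAGAAT (42 and 2) and TGCTCTTCTGAGCAGTAATTAGG next to trnP-UGG on the other strand (23 and 2).

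With so few counts the size of a change is loosely bounded, and the pooled ratios are given with 95% counting intervals. These intervals cover counting error only and leave out the spread between replicates. The control to heat ratio was 248 (68.5 to 2054) for TGTGACCAATTAACCAACCAACAAAACTAC, 267 (47.7 to 10584) for TTGCGTCGTTGTGCCTGGGCTGTGAGGGCT, 158 (28.1 to 6287) for ACTTTGTATCGCGCACATAACT and 47.5 (8.22 to 1903) for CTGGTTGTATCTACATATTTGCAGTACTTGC. The heat to control ratio was 35.6 (5.85 to 1460) for CCGAACTGAACTAAGAGC, 28.8 (7.48 to 245) for ATGGGGTAGAGCCAAAGAAT and 15.8 (3.89 to 138) for TGCTCTTCTGAGCAGTAATTAGG.

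The counts of calls depended on the tool: DESeq2 called 645 sequences higher and 177 lower. Without heat replicate 1 there were 1178 calls and without heat replicate 2 there were 1167.

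Read length also differed between the groups. Reads of 24 nt held 7.52% ± 0.330 of the control counts and 12.2% ± 0.710 of the heat counts, and reads of 23 nt 7.09% ± 0.134 and 9.56% ± 0.172 (SD, n = 2 each). Reads of 29 to 32 nt held 17.7% ± 3.14 in control and 10.4% ± 1.42 in heat, and reads of 36 nt 1.68% ± 0.200 and 0.306% ± 0.0268. No list held reads of 33 to 35 nt, and 36 nt was the longest read. A read of 36 nt may therefore stop short of the end of its RNA. Reads under 15 nt held 6.77% ± 0.792 in control and 4.86% ± 0.0487 in heat. For these 5 lengths both heat libraries lay on the same side of both controls (exact permutation p = 0.33, the smallest possible). As a group, reads of 24 to 28 nt rose by 4.22 points, but by 0.411 without the 10 most abundant sequences and by 1.12 over distinct sequences, while the fall of 1.37 points at 36 nt became 2.23 without those 10. The 5-prime base showed no separation of the groups: G began 40.2% ± 4.39 of the control reads and 39.6% ± 4.90 of the heat reads, A 25.8% ± 1.71 and 26.3% ± 0.861, C 17.1% ± 2.28 and 16.5% ± 2.52, and T 16.7% ± 0.390 and 17.4% ± 1.51 (exact permutation p 0.667 for C and G and 1.0 for A and T).

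**Figure D3:**
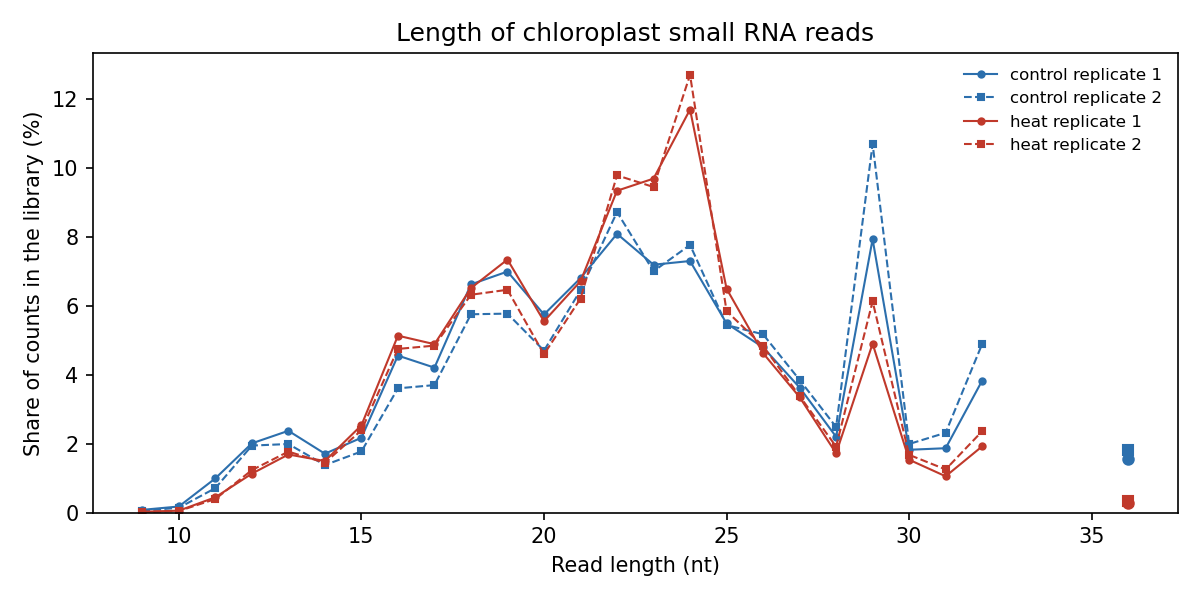
Share of counts in each Chinese cabbage library (%, vertical axis) by read length (nt, horizontal axis), a line per library with isolated points at 36 nt. The heat libraries peak at 24 nt with 11.7% and 12.7%, and the control libraries at 29 nt, or at 22 nt in control replicate 1, with 10.7% and 8.08%.

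Most transfer RNA reads in the Chinese cabbage lists were 5-prime fragments. In control 88.4% ± 2.11 of the transfer RNA counts started within 1 nt of the mature 5-prime end, and in heat 78.5% ± 3.01 (SD, n = 2 each; exact permutation p = 0.33, the smallest possible). Reads ending within 3 nt of the encoded 3-prime end were rare, at 0.657% ± 0.0737 in control and 1.06% ± 0.0442 in heat. The Chinese cabbage lists held 0 reads ending in the CCA added to mature transfer RNAs, against 12238 counts in Ler. Fragments with that end may be missing from the lists, so the 5-prime share may depend on how they were made. The trnD-GUC gene held 49.2% of all transfer RNA counts, and without it the 5-prime share was 75.0% ± 1.61 in control and 65.8% ± 3.10 in heat. In rrn4.5 the reads ended within 3 nt of the 3-prime end in 99.4% ± 0.111 of counts in control and 99.5% ± 0.108 in heat. In rrn5 this share was 47.8% ± 0.961 and 46.0% ± 2.21, and in rrn16 and rrn23 it was under 1% of counts in both groups.

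The Ler library, a single sample of another species with no replicate, was dominated by ribosomal RNA. Ribosomal RNA held 63.3% of its counts (95% interval 63.2% to 63.4%), transfer RNA 9.80% (9.73% to 9.86%) and protein-coding genes 6.68% (6.63% to 6.74%), and 13.9% could not be placed. The 5 most abundant genes were rrn23 (31.5%), rrn16 (22.0%), rrn5 (8.30%), psbA (3.12%) and rbcL (1.75%). Its most abundant sequence was AGATGAGTGCTCTCCT, nucleotides 2795 to 2810 of rrn23, with 10910 counts. It was followed by AGTTACTAATTCATGATCTGGCAT, which overlapped the matched part of ndhB by 12 nt (10048 counts), GCGGAAAAATAGCTCGACGCCAGGATG of rrn5 (4831), TGGGGCGTAGCCAAGCGGTA of trnQ-UUG (4152) and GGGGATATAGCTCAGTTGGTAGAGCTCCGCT of trnA-UGC exon 1 (2612). Reads of 24 to 28 nt held 31.3% and of 29 to 32 nt 12.8%, with 0 reads of 36 nt. The 5-prime base was G in 36.3% and A in 32.6% of the reads.

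Sequences common to the Ler and control Chinese cabbage lists were counted to ask what both species share. Of sequences with at least 10 counts, 11124 in Ler and 16707 in the pooled controls, 3853 occurred in both and held 41.6% of the Ler counts and 68.7% of the control counts. Across these sequences, which are not independent replicates, the Spearman correlation of counts was 0.26. Species, tissue, sequencing centre and the making of the lists differ together between these libraries, and no test between them was made.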

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

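The test of substitution neighbours and the comparisons of the 36-nt ratio between RNA classes were chosen after the results were seen.

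A signal outside the heat comparison appeared in the Ler library. It held 12238 counts of transfer RNA reads that ended in a CCA not encoded in the gene, the end added to mature transfer RNAs, against 75 counts that ended at the encoded 3-prime end. The Chinese cabbage lists held 0 such CCA counts and 209 to 544 counts at the encoded end. The Ler list also held 11216 counts in sequences that differed by 1 base from its 100 most abundant placed sequences and could not be placed themselves, 10.25% of the counts of those sequences, while each Chinese cabbage list held 0. A stricter match to the chloroplast when the Chinese cabbage lists were made is a candidate explanation for both, but the share of 10.25% restates the pattern that prompted it and does not decide, and species and sequencing centre differ as well. Reads with an undetermined base (N) held 1.34% to 1.46% of the Chinese cabbage counts and 1.03% of the Ler counts. With 1 mismatch allowed, the placed share of the Chinese cabbage counts went from 90.97% to 93.29% up to 92.19% to 94.48%. The Chinese cabbage lists thus do hold some reads that match only with 1 mismatch. No biological explanation was tested.

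Reads of 36 nt took a smaller share of the heat libraries, 0.182 of that in control. A loss of long inserts in library making or trimming was predicted to give a ratio under 0.67 in ribosomal RNA, transfer RNA and protein-coding reads alike, and the highest of the 3 ratios was 0.3847, so this explanation remains open. The ratios were 0.0967 for transfer RNA and 0.3847 for ribosomal RNA, but the first rested mostly on the 36-nt fragment of trnL-UAA. Without the most abundant 36-nt sequence of each class they were 0.2897 and 0.3892, and over the library pairs they ran from 0.2715 to 0.3088 and from 0.312 to 0.4866. A few abundant sequences as the whole cause are argued against by a ratio of 0.3031 without the 10 most abundant 36-nt sequences, and an effect of heat may contribute but was not tested apart from the libraries.

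Transfer RNA genes and photosynthesis genes moved apart, with a difference of 0.99 between their median log2 fold changes, which was not itself tested. Of the genes, 12 of 30 for transfer RNA and 24 of 44 for photosynthesis did not pass, and the NDH genes among the latter had a median of 0.18. Without the most abundant sequence of each gene the difference was 0.945 and with reads of 18 to 25 nt 0.893. The first value argues against 1 sequence per gene as the whole cause, but overlapping versions of that sequence stayed in. The second argues against reads outside that window as the whole cause. It cannot decide on the shift within the window, such as the rise at 23 and 24 nt. In single genes the most abundant sequence did weigh: trnA-UGC went from 0.84 to 0.34 and trnP-UGG from 0.85 to 0.41 without it. The lowest difference of medians among the 4 pairs of a heat and a control library was 0.615, above 0 in 4 of 4 pairs. A response to heat is a hypothesis that these values leave open, beside a difference between plant lines that the labels number apart, which could not be tested.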

How the results depend on the processing

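The tests on contigs, on stretches outside genes, without reads of 36 nt, without ycf2 and with factors from protein-coding genes were chosen after the data were seen. No call turned direction among the 1914 sequences or the 50 genes on contigs under any alternative run. At the depth and number of libraries here, 22% of sequences changed by 2-fold and 82% of those changed by 4-fold were recovered in simulated data. Depth itself was not varied.

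Against 1914 sequence calls, there were 1140 without the filter (977 of the 1914 among them), 774 with a minimum count of 50 (596 among them, with fewer sequences tested) and 822 in DESeq2 (821 among them). Leaving out a library gave 1167 (without heat replicate 2) to 1415, with 1178 without heat replicate 1. When a library was left out, genes on contigs ranged from 0 calls without either heat library, where the lone heat sample is assumed to vary like the controls, to 50. At an unadjusted p under 0.05 those 0 calls were 39 and 42. With all libraries the calls ran from 43 in DESeq2 to 62 with the replicate block. The primer families ranged from 0 calls without either heat library (0 at an unadjusted p under 0.05) to 4 without control replicate 1, with 4 on list totals and 5 when 1 mismatch was allowed, where trnL-UAA turned to -0.89 (adjusted p = 0.0192 in edgeR). A minimum count of 50 left trnF-GAA and trnL-UAA untested. Of 12 gene lists 1 passed in the directional fry test and 10 in its mixed test, 3 in camera with a preset correlation and 0 with an estimated one, and 0 to 1 in directional fry when a library was left out (0 without either control library). Except where fewer samples or sequences were tested, or where 1 mismatch let in the 36-nt trnL-UAA sequence, the cause was not tested.

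The stretches outside the placed genes changed balance with their scaling. With the factors of the sequence fit 217 were higher and 30 lower in heat, and with TMM or RLE factors of their own 96 and 120, or 84 and 124. DESeq2 called 133, and leaving out a library gave 157 (without heat replicate 2) to 300.

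Same-numbered replicates deviated together with a correlation of 0.31 over sequences and 0.30 over genes, but the labels share only a number. In replicates 1 and 2 ribosomal RNA held 47.2% and 40.6% of the counts in heat and 53.6% and 47.4% in control. Transfer RNA held 36.1% and 41.3% in heat and 30.1% and 35.9% in control. With the replicate number as a block, 1724 sequences rose and 1002 fell, and 30 genes on contigs rose and 32 fell. With it 4 primer families passed, and 261 outside stretches rose and 43 fell. Of the gene lists, 1 passed in directional fry (ATP synthase, adjusted p = 0.00659). In camera transfer RNA (adjusted p = 4.07e-09), photosystem II (0.0186) and ATP synthase (0.0186) passed. Among the gene and sequence calls gained with the block were rrn4.5 (log2 -0.36, adjusted p = 9.83e-05 in edgeR), trnD-GUC (-0.37, 0.000177), trnL-UAA (-0.22, 0.0155) and GGGATTGTAGTTCAATTGGTCAGAGCACC (-0.74, 2.24e-12).

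Some genes turned direction. The rrn5 change was 0.074 on list totals, 0.135 with factors from protein-coding genes, and -0.262 to 0.028 when a library was left out. The trnL-UAA change was 0.026 with factors from protein-coding genes, 0.185 with reads of 18 to 30 nt and 0.241 without reads of 36 nt, which removes its main 36-nt fragment. Leaving out a library took trnH-GUG from -0.034 to 0.154, rpl23 from -0.034 to 0.498, CAGACCGGTAGACTTGAAC from -0.31 to 0.10 and the rrn16 primer family from -0.729 to 0.029. The cause was not tested.

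For shares, the heat minus control difference in ribosomal RNA was -0.861 points over distinct sequences, in protein-coding genes -4.19, and in reads of 24 to 28 nt 1.12 (4.22 over counts). Without the 10 most abundant sequences it was 9.82 for transfer RNA, -1.17 for protein-coding genes, 0.411 for 24 to 28 nt and -2.23 for 36 nt. Over distinct sequences the 5-prime base A turned to -0.324 and G to 0.652, and when a library was left out A ran from -0.677 to 1.74, C from -2.42 to 1.14, G from -4.05 to 2.87 and T from -0.359 to 1.78. In Ler the distinct sequences were 27.1% ribosomal RNA, 2.31% transfer RNA and 13.8% protein-coding. Sequences shared with the controls numbered 18807 at 2 counts or more and 576 at 50 or more. Reads wholly inside 1 gene were not run for the primer families, which have no gene ends.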

Other observations

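All tests of contig stretches outside the placed genes were chosen after the data were seen, and their balance depends on the scaling.

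The most abundant stretch outside the placed genes lay at the edge of the matched part of ndhB, a gene of the NDH complex. It was led by AGTTACTAATTCATGATCTGGC with 82.5% of its counts, which overlapped that part by 10 of its 22 nt and had its midpoint outside. It went from 17514 ± 4543 CPM in control to 33638 ± 7421 CPM in heat (SD, n = 2 each), a log2 fold change of 0.94 with the scaling of the sequence fit (SE 0.24, adjusted p = 0.0156 in edgeR). A stretch with no placed gene, led by AAACAAGAATTCTTGAACAGCG, went from 1367 ± 58.3 to 4962 ± 212 CPM (log2 1.86, SE 0.14). The next stretches are named by their most abundant sequence, while each change is that of all reads outside genes on that contig strand. The stretch led by a sequence 15 nt upstream of psbH, a photosystem II gene, rose by 1.46 (SE 0.25). That sequence held 18.1% of its counts. Stretches led by sequences upstream of ribosomal RNA went the other way. That led from 49 nt before rrn23 (27.1% of its counts) fell by 1.27 (SE 0.15), and that led from 10 nt before rrn16 (27.1%) fell by 0.98 (SE 0.15). The stretch led by a sequence 37 nt upstream of rbcL (7.6%) did not pass (log2 -0.23, adjusted p = 0.18). With TMM factors of their own, the ndhB stretch did not pass (log2 0.26, adjusted p = 0.491) and the rbcL stretch did (log2 -0.91, adjusted p = 5.51e-07). The AAACAAGAATTCTTGAACAGCG stretch (1.18), psbH (0.78), rrn23 (-1.95) and rrn16 (-1.65) passed in the same direction. Of 500 stretches, 217 rose and 30 fell with the scaling of the sequence fit, and 238 rose and 39 fell on list totals. With TMM factors of their own 96 rose and 120 fell. Those factors centre the stretches (median log2 change 0.036, against 0.729 with the sequence fit), so that balance cannot show or deny a common shift. As a share of counts the stretches stood at 7.36% and 8.48% in heat and 4.51% and 5.52% in control. Which scaling is right was not tested.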
